A study of Caenorhabditis elegans with 2 samples.

How the data were processed

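The measurement was chromatin immunoprecipitation followed by sequencing (ChIP-seq) of UNC-86, a POU homeodomain transcription factor of neurons, in whole Caenorhabditis elegans hermaphrodites. The worms were L1 larvae, the first larval stage, collected 6 hours after synchronization by starvation of bleached embryos. The strain carries an unc-119 mutation on chromosome III and an integrated transgene with UNC-86 fused at its C terminus to GFP. The labels describe the tag both as eGFP and as GFP-FLAG, and name both an antibody to GFP and unc-86 as the target. An antibody to GFP, as the sample descriptions state, was taken as the reagent, with unc-86 as the protein pulled down. There were 2 biological replicates of 1 group, so no conditions were compared. A control is named in the labels, and its identity was not analysed here.

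The deposited data were peak lists. Per the listing deposited beside the samples, each replicate's list was made from that replicate's alignment and a control, a pooled list from both alignments together, and an optimal list by the irreproducible discovery rate (IDR) procedure from these. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The signal value of each peak is the authors' own, and its scaling is not given in the sources used here. It was used only to describe, rank or filter peaks within a list. The −log10 q value in the authors' lists had the same value, 3.79, at all 2987 peaks of the optimal list and was not used for ranking. Summits were taken from the deposited offset from the start of each peak. The lists on the ce11 build were used, with the lists on the older ce10 build as an alternative, and no coordinates were converted between builds. All 2987 optimal peaks on ce11 were found in the pooled list of 20768 peaks, and they were the 2987 with the highest signal value there. The optimal list on ce10 held the 3637 highest of 20775. The replicate lists, relaxed lists that include background for IDR, held 29587 peaks for replicate 1 and 25172 for replicate 2. The pooled list also includes background for IDR. Of the optimal peaks, 74.9% were 396 bp long. Peak lists hold no read counts, so the depth of each library is unknown, and intervals on shares cover the counting of peaks or genes only.

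Peaks were set against the WBcel235 assembly, the reference of the ce11 build, with the Ensembl gene annotation of release 115, which lists 19973 protein-coding genes on the nuclear chromosomes. No peak ended beyond a chromosome's length in that assembly. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1. The replicates were compared by the share of optimal peaks that a peak of each replicate's 2987 strongest overlapped by at least 1 bp, set beside 1000 random placements of the peaks within their chromosomes. Ranks were compared by Spearman's rho over optimal peaks, with 1000 resamples of regions for its interval. A summit was at a promoter if it lay from 1500 bp upstream to 500 bp downstream of an annotated 5' transcript end of any gene. Other summits were assigned to exon, intron or intergenic sequence, and each share was tested against the placements by a two-sided permutation test, whose smallest p is 0.002.

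Gene lists, 17 of symbols and 13 of gene families, were tested by Fisher's exact test, two-sided, against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 30 lists. Beside it, each count was placed among 10000 random lists matched on upstream intergenic length in 10 bins, where the smallest two-sided p is 0.0002. For 6 sequences and 3 controls made by reversing a sequence, the share of windows of 75 bp either side of the summit with the sequence on either strand was set against both flanks centred 500 bp away by Fisher's exact test, adjusted over the 9. Peaks per chromosome were tested by an exact binomial test against length. Peaks are clustered and share promoters, so these p-values overstate the evidence. Intervals on shares are exact (Clopper-Pearson) 95% intervals. For errors between replicates, each replicate's own 2987 strongest peaks were put through the same step and given as mean ± SD.

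The genes named are unc-86 and unc-119, the nearest protein-coding gene to each of the 10 strongest optimal peaks, with the second gene where the summit lies between divergent 5' ends, and 9 genes known as UNC-86 targets. In each symbol list up to 4 members with the strongest promoter peaks are named, and up to 2 without a peak where fewer than 4 had one. In each family list past the threshold the 3 strongest are named. This rule, the lists, the sequences, the tests and the alternatives marked as planned were fixed before the data were examined. The alternatives fixed in that way changed the overlap rule, the list length, the build, the signal threshold, the promoter window, the assignment of peaks to genes, the summit window and the flanks, and left out each replicate in turn. Alternatives chosen after seeing the data were 5' ends of protein-coding genes only, as many ce11 peaks as the ce10 optimal list holds, and an added list of other genes used in all cells. The overlap, promoter, gene list and sequence steps were tested on simulated data. All 2431 displaced copies of peaks were found by the overlap step, which gave the same calls as a direct search over 300 peaks. All 120 simulated gene lists of 80 genes with extra hits passed, beside 5 of the other lists. The symbol lists were shorter than this, and real genes can share a peak, while simulated hits were drawn gene by gene. Recovery and false calls in short lists, or where peaks are shared, were therefore not measured. A sequence planted in a small share of summits was called in 19 of 20 runs, beside 2 calls of other sequences. Simulated summits and flanks had the same base composition, while the real ones had 45.2% and 35.8% G and C bases. This simulation therefore does not measure calls that arise from that difference.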

Results

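Binding of UNC-86 was mapped in L1 larvae by ChIP-seq against a GFP tag on the protein. UNC-86 specifies the identity of several classes of C. elegans neurons, among them the touch receptor neurons. The data were lists of peaks from 2 biological replicates, 1 pooled list and 1 optimal list of 2987 peaks that passed the authors' IDR procedure. All values given for a peak are the authors' signal values, which rank peaks within a list, and coordinates are on the ce11 build. The read depth of the libraries is unknown.

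The unc-86 gene itself lay among one of the densest clusters of peaks in the genome. unc-86 (WBGene00006818) lies on chromosome III from 8212740 to 8216336, minus strand, and 12 optimal peaks had their summits within 20 kb of it. In windows of this size across the genome the median was 1 peak, and 99.985% of windows held fewer than 12. The strongest peak, at 8211572 to 8211984 with a signal of 602, lay downstream of the 3' end of the gene and ranked 87 of all optimal peaks. In the promoter window, summits lay 83 bp (signal 305) and 1117 bp (signal 356) upstream of the 5' end, and a further peak with a signal of 147 lay inside the gene at 8215145. Away from the gene, the peaks with signals of 534 and 376 lay in rfs-1, the latter also in fbxl-1. All 12 peaks were in the strongest 2987 of both replicates. The relaxed lists held 33 peaks here in replicate 1 and 36 in replicate 2. At unc-119 (WBGene00006843, chromosome III from 10902641 to 10908935), which is mutated in the strain used, 2 optimal peaks lay inside the gene, with signals of 76.4 and 128. These were counted within 5 kb of the gene, and 89.4% of windows of that size (16.3 kb) held fewer. A transgene can carry extra copies of these regions, which peak lists do not show.

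**Figure D1:**
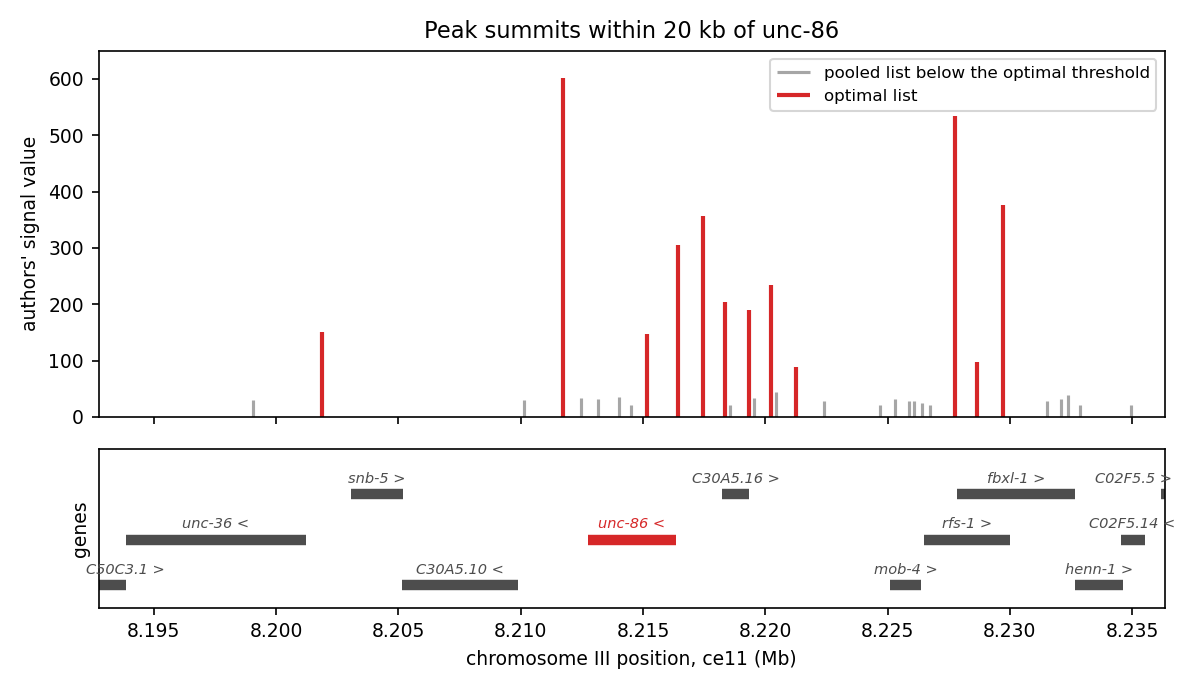
Summits of pooled peaks within 20 kb of unc-86 on chromosome III of ce11 (x axis, Mb), with the authors' signal value as the height of each line (y axis) and protein-coding genes below, > and < marking strand. The 12 optimal peaks, in red, reach a signal of 602, and 21 weaker peaks of the pooled list, in grey, lie below the optimal threshold of 66.4.

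The replicates placed most strong peaks at the same sites. Of the 2987 optimal peaks, 2514 (84.2%, 95% interval 82.8 to 85.5) were overlapped by a peak among the strongest 2987 of both replicates, while random placement gave 1.71%. The optimal list was made by IDR from these same replicates. The share, and the rank agreement across optimal peaks, are therefore not independent of how the peaks were chosen. Replicate 1 covered 90.3% of them, replicate 2 covered 93.3%, and 16 peaks were covered by neither. Of the strongest peaks of replicate 1, 84.5% were overlapped in replicate 2, and 84.7% the other way. The peak at rpl-3 was the strongest in both replicates, with signals of 807 and 902, and the peak at mec-7, a touch receptor gene, had 66.1 and 91.0. Across optimal peaks the signals gave Spearman's rho of 0.859 (95% interval 0.846 to 0.870) and Pearson's r of 0.900 on log2 values. Regions are not independent replicates, so no p was computed. Over the 12994 pooled peaks that both relaxed lists held, rho was 0.728. Of the optimal peaks, 99 (3.31%) differed by over 2 fold from the median ratio of the replicates. The share covered by both lists fell to 72.0% when 50% reciprocal overlap was required.

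**Figure D2:**
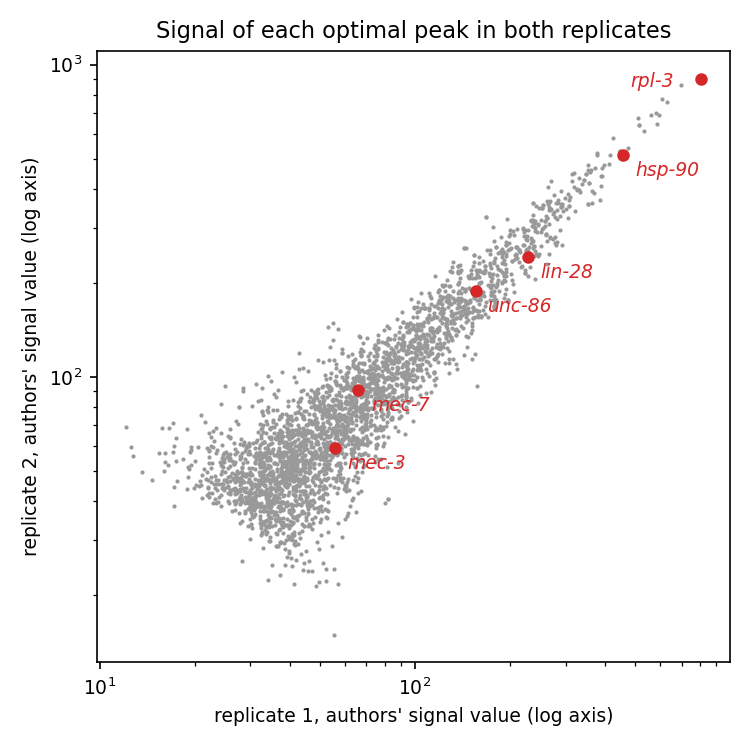
Authors' signal value of the strongest overlapping peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale) for each of the 2987 optimal peaks, as grey points, with the promoter peaks of 6 genes in red. The points follow a diagonal, with Spearman's rho of 0.859, from mec-3 (55.8 and 59.2) to rpl-3 (807 and 902) among the genes marked, and spread more widely at low signal.

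The strongest peaks lay at ribosomal protein genes and other genes outside the lists of neuronal genes. The highest signal, 1708, was 283 bp upstream of rpl-3 (WBGene00004414, chromosome III, peak from 3867413 to 3867737), which encodes a ribosomal protein. Next, with a signal of 1555, came a peak between tasp-1 and K01G5.10, then one with 1396 between Y17G9B.5 and rpl-20. A peak with a signal of 1371 lay on chromosome V in an exon of the non-coding gene linc-128, 4773 bp upstream of cmd-1, the calmodulin gene, outside its promoter window. A peak in an intron of Y111B2A.12 had 1276, and one between tag-340 and nhl-2 had 1274. The peak 449 bp upstream of rpl-35 had 1255. The divergent gene on its far side, ZK652.8, lay 11049 bp away and had no optimal peak. The last of the 10 strongest were at cdc-48.1, an AAA ATPase (1231), in an intron of pqn-41 (1186) and 565 bp upstream of egg-5 (1156). Of these 10 peaks, 6 lay on chromosome III and none had AATGCAT, an element bound by UNC-86 with MEC-3, within 75 bp of the summit.

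Summits concentrated at promoters and avoided exons. At promoters lay 2388 of 2987 summits (79.9%, 95% interval 78.5 to 81.4), against 53.0% ± 0.885 (SD over 1000 random placements), a ratio of 1.51. Exons outside promoter windows held 1.00% against 15.4% by chance, and introns held 8.001% against 19.1%. Intergenic sequence held 11.05% against 12.5% (permutation p = 0.018). For promoters, exons and introns the two-sided permutation p was 0.002, the smallest the placements can give. The replicates' own strongest peaks gave 79.9% ± 1.02 at promoters (SD, n = 2), so the excess over chance was far larger than the spread between replicates. With 5' ends of protein-coding genes only, a setting chosen after seeing the data, the share was 65.0% against 39.1%. In the replicate 1 list the difference in intergenic share was not past the threshold (11.6% against 12.4%, permutation p = 0.150), nor was it with as many peaks as the ce10 list (p = 0.174), a window of 1000 bp up to 250 bp down (p = 0.262) or protein-coding 5' ends only (p = 0.573).

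Ribosomal protein genes had the highest share of promoter peaks when a summit counted for every gene whose window held it. Of 76 such genes, 64 had one (84.2%, 95% interval 74.04 to 91.6), against 12.8% of other protein-coding genes (Fisher's exact test, adjusted p = 1.3e-43), led by rpl-3, rpl-20 and rpl-35. Each replicate alone gave 81.6% ± 1.86 (SD, n = 2). In all, 2612 of 19973 protein-coding genes (13.1%) had a promoter peak. Of 14 stress response genes, 6 had one (42.9%, exact test, adjusted p = 0.019), with signals of 970 at hsp-90, 835 at hsp-1, 541 at hsp-3 and 173 at hsp-16.2, which all encode chaperones. The peak at hsp-16.2 was also counted for hsp-16.41, outside the rule for named genes, so the 6 genes rest on 5 peaks. Of 80 histone genes, 19 had one (23.8%, exact test, adjusted p = 0.023), led by his-37 (655) and by his-67 and his-68, which share a peak (367). Against random lists matched on upstream intergenic length the histone share was not past the threshold (20.2% in matched lists, permutation test, adjusted p = 0.849), while the ribosomal and stress response shares were (adjusted p = 0.0015 and 0.040). With each peak given only to its nearest 5' end, the ribosomal share fell to 50% (Fisher's exact test, adjusted p = 3.8e-19), below the pan-neuronal 66.7% and the heterochronic 57.1%. In that setting the stress response and histone shares (28.6% and 16.25%, against 8.95% and 8.94% of other genes) were not past the threshold (both adjusted p = 0.085 by Fisher's exact test).

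Pan-neuronal genes carried peaks, and so did genes of developmental timing. Of 21 pan-neuronal genes, 14 had a promoter peak (66.7%, 95% interval 43.03 to 85.4, Fisher's exact test, adjusted p = 1.5e-07). The highest signals were 475 at egl-3, which encodes a neuropeptide convertase, 356 at unc-64 (syntaxin), 281 at unc-11 (a clathrin adaptor) and 274 at rgef-1. The replicates gave 13 and 14 genes, a mean of 64.3% ± 3.37 (SD, n = 2). Of 7 heterochronic genes, 5 had a peak (71.4%, adjusted p = 0.0032 by Fisher's exact test): lin-28 (473), lin-41 (245), lin-42 (86.4) and lin-14 (83.1) had the highest signals, and the fifth, lin-46, outside the rule for named genes, had 70.2. Each replicate alone gave 4 of 7. Among the optimal peaks with signals above the median 28.6% of the heterochronic genes had a peak (exact test, adjusted p = 0.263), and with a window of 1000 bp up to 250 bp down 42.9% had one (adjusted p = 0.093).

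Of the genes of the touch receptor neurons, which UNC-86 and the LIM homeodomain protein MEC-3 specify, 5 of 13 had a promoter peak (38.5%, 95% interval 13.9 to 68.4). Against 13.1% of other genes this was not past the threshold in the planned test (Fisher's exact test, adjusted p = 0.054), and both replicates gave the same count of 5. Against random lists matched on upstream intergenic length it was not past the threshold either (permutation test, adjusted p = 0.094). Over 8 other settings the adjusted p of Fisher's exact test ranged from 0.0038 to 0.568 and passed the threshold in 6, and that of the matched permutation test ranged from 0.0082 to 1. The lowest Fisher value, and 1 of the 6 passes, came from as many peaks as the ce10 optimal list holds, a setting chosen after seeing the data. Among planned settings the lowest was 0.015 (Fisher's exact test, any overlap of the peak with the window). The members were mec-7, which encodes a beta-tubulin (161, chromosome X, summit 7776808), mec-10, a degenerin channel subunit (130, 17 bp upstream), mec-3 (113.5, chromosome IV, summit 10461996, 129 bp upstream), mec-14 (108, 428 bp upstream) and, outside the rule for named genes, mec-2 (72.8). In replicate 1 the peak at mec-2 was not among the strongest 2987. There mec-6 had a promoter peak instead, which it lacked in replicate 2, so the equal counts of 5 do not cover the same genes. AATGCAT lay within 75 bp of the summit at 4 of these 5 peaks, namely at mec-3, mec-7, mec-10 and mec-14, against 87 of the 2982 other optimal peaks (2.92%). This comparison was chosen after the values were seen, among 21 lists with a peak (Fisher's exact test, p = 3.9e-06, adjusted p = 8.3e-05). AATGCAT was already known as an element bound by UNC-86 with MEC-3, which specify these neurons. The p-value is therefore not evidence independent of what was known of these genes.

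Genes known as targets of UNC-86 in other neurons had no optimal peak at their promoters. These were tph-1 and cat-1 of serotonin neurons, unc-17 and cho-1 of the acetylcholine pathway, cfi-1 (a transcription factor), eat-4 (the glutamate transporter of synaptic vesicles) and, in touch neurons, mec-4. Of the serotonin pathway, 1 of 6 genes had an optimal peak, ptps-1 (279), whose summit lay in the neighbouring gene ain-2. None of 5 acetylcholine pathway genes (unc-17, cha-1), 9 genes of IL2, URA, URB, FLP and PVD identity (klp-6, cfi-1), 6 Hox genes (ceh-13, lin-39), 5 GABA pathway genes (unc-25, unc-47) or 5 dopamine pathway genes (cat-2, dat-1) had one. Of 29 transcription factors of neuronal fate, 2 did: ast-1 (149) and mec-3, while ttx-3 and cfi-1 did not. Of 19 cilium genes, 1 did, dyf-3 (75.1), while osm-1 and osm-5 did not. None of these lists differed from other genes past the threshold, and lists of 5 to 9 genes allow shares of up to 33.6% to 52.2% when no member has a peak.

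Chemoreceptor, F-box, neuropeptide, nuclear hormone receptor and collagen genes carried few peaks. Of 1310 chemoreceptor genes, 13 had a promoter peak (0.992%, Fisher's exact test, adjusted p = 2.6e-61), with srh-16 (315), sri-5 (302) and srt-11 (185) the strongest. Shares were also low for F-box genes (7 of 322, exact test, adjusted p = 4.7e-11, among them fbxb-85 with 543, fbxa-90 with 392.5 and fbxb-58 with 313), neuropeptide genes (6 of 140, adjusted p = 0.0039, among them ins-39 with 345, nlp-7 with 168 and nlp-76 with 134), nuclear hormone receptors (17 of 269, adjusted p = 0.0030, among them nhr-47 with 456, nhr-48 with 309 and nhr-1 with 308) and col collagens (8 of 156, adjusted p = 0.0066, among them col-38 with 232, col-71 with 203 and col-72 with 141). None of 31 major sperm protein genes had one (Fisher's exact test, adjusted p = 0.070, and 0.040 against matched lists by a permutation test). Over 8 other settings the adjusted p of Fisher's exact test for this list ranged from 0.019 to 0.423 and passed the threshold in 3. With each peak given only to its nearest 5' end, the neuropeptide and nuclear hormone receptor shares (3.57% and 5.20%, against 9.01% and 9.02% of other genes) were no longer past the threshold (both adjusted p = 0.085 by Fisher's exact test). Lists of other tissues did not differ from other genes past the threshold (Fisher's exact test, adjusted p from 0.450 to 1). No optimal peak was found at 7 pharynx genes (myo-1, myo-2), 13 intestine genes (elt-2, elt-7) or 14 hypodermis genes (dpy-7, dpy-10), while 1 of 14 body wall muscle genes (act-4 with 132, not myo-3 or unc-54) and 2 of 16 germline genes (mes-2 with 212 and spo-11 with 106, not pgl-1 or pgl-3) had one. Remaining lists also did not pass: 4 of 63 ceh homeobox genes, 1 of 29 degenerin channels, 1 of 32 acetylcholine receptor subunits, 6 of 61 potassium channels and 2 of 25 innexins.

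**Figure D3:**
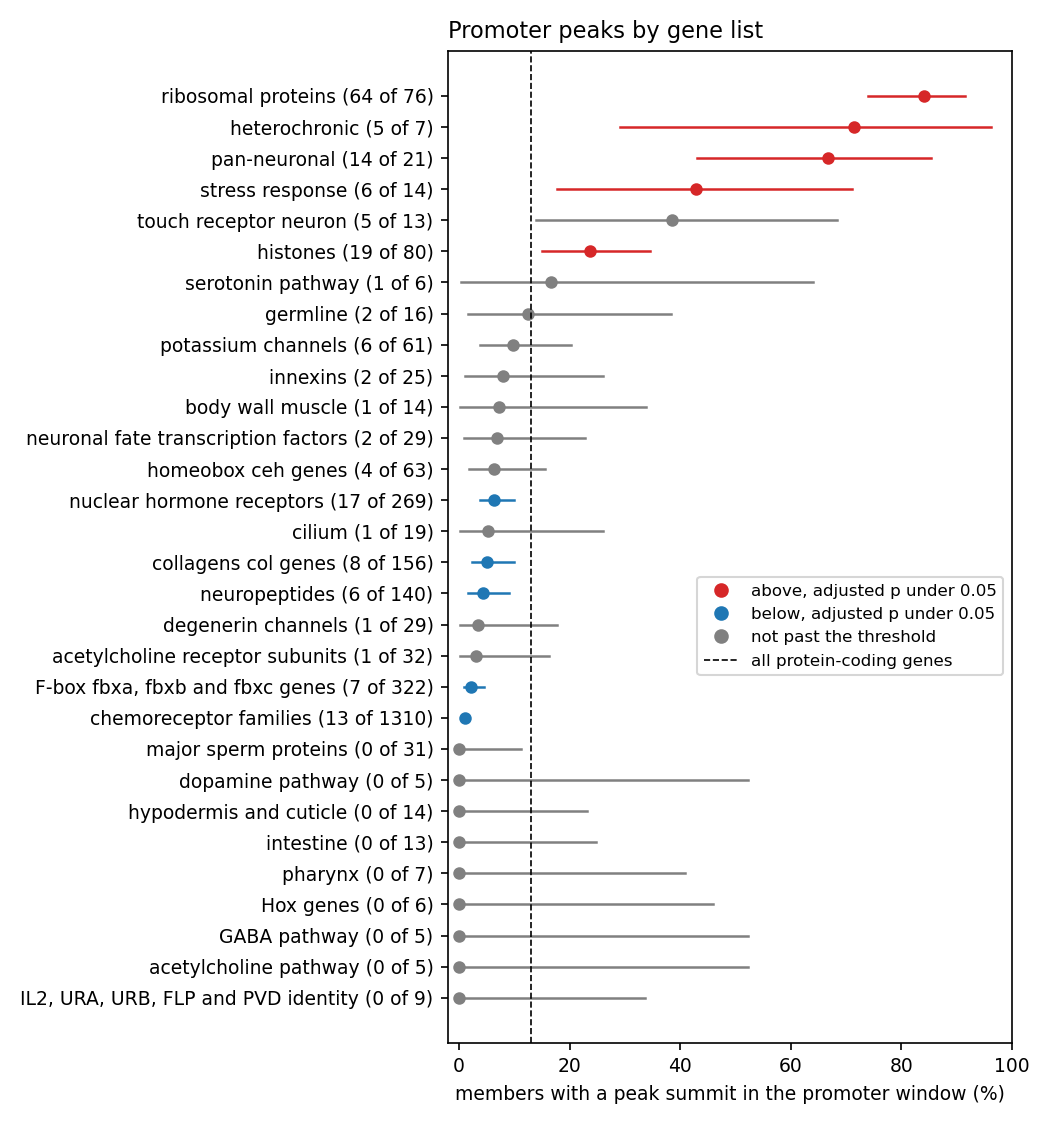
Share of each list's members with an optimal peak summit in the promoter window (x axis, %), with exact 95% intervals as lines and the count beside each list's name. Red and blue mark lists above and below other protein-coding genes at an adjusted p under 0.05, grey marks lists not past it, and the dashed line marks the 13.1% of all protein-coding genes; ribosomal proteins lead with 84.2%.

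Among non-coding genes, those of small nucleolar RNAs and transfer RNAs had promoter peaks more often than protein-coding genes. Of 346 snoRNA genes, 116 had one (33.5%, 95% interval 28.6 to 38.8, Fisher's exact test, adjusted p = 1.5e-21), and of 612 tRNA genes 135 had one (22.1%, adjusted p = 4.0e-09). For 129 snRNA genes (13.95%) and 261 miRNA genes (11.5%) the share was not past the threshold (exact test, adjusted p = 0.793 and 0.647). Of 15363 piRNA genes, 333 had one (2.17%). Many snoRNA genes lie inside or beside other genes, and a summit was counted for every gene whose window held it.

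Repeats of GA were the commonest of the sequences examined at summits, and AATGCAT was enriched to a smaller degree. GAGAGA lay within 75 bp of 36.3% of summits (95% interval 34.6 to 38.04) and in 7.499% of flank windows, a ratio of 4.84 (Fisher's exact test, adjusted p = 2.9e-240). AATGCAT lay at 91 of 2987 summits (3.05%, 95% interval 2.46 to 3.73) and in 1.93% of flanks, a ratio of 1.58 (exact test, adjusted p = 0.0022). The replicates' own peaks gave ratios of 1.66 ± 0.0292 (SD, n = 2). This ratio ranked 33 among 1344 sequences with the same number of A or T and of G or C bases. The core ATGCAT had a ratio of 1.66 (exact test, adjusted p = 9.7e-06, rank 14 of 492), while the POU octamer ATGCAAAT had 0.974 (adjusted p = 0.920). The homeodomain core TAATTA was rarer at summits than in flanks, 4.52% against 7.78% (exact test, adjusted p = 9.6e-09), and the E box CACGTG was more frequent, 4.55% against 3.05% (adjusted p = 0.00096), although 236 sequences of the same composition had a higher ratio. TAATTA ranked 12 among 36 sequences made of A and T only, so most of these had a lower ratio still. Among peaks with signals above the median it ranked 25 of 36, and most had a higher ratio. None of the 3 reversed control sequences was past the threshold in the planned test. Summit windows had 45.2% G and C bases and flanks 35.8%. The AATGCAT ratio was not past the threshold among peaks with signals above the median (1.5, exact test, adjusted p = 0.065), within 30 bp of the summit (1.57, adjusted p = 0.085) or with flanks 1000 bp away (1.32, adjusted p = 0.059). Among peaks with signals above the median, ATGCAAAT was rarer at summits (ratio 0.444, exact test, adjusted p = 0.030), and so was the control TACGTAA (0.286, adjusted p = 0.023). With flanks 1000 bp away the control TAAACGTA was rarer (0.296, exact test, adjusted p = 0.024).

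**Figure D4:**
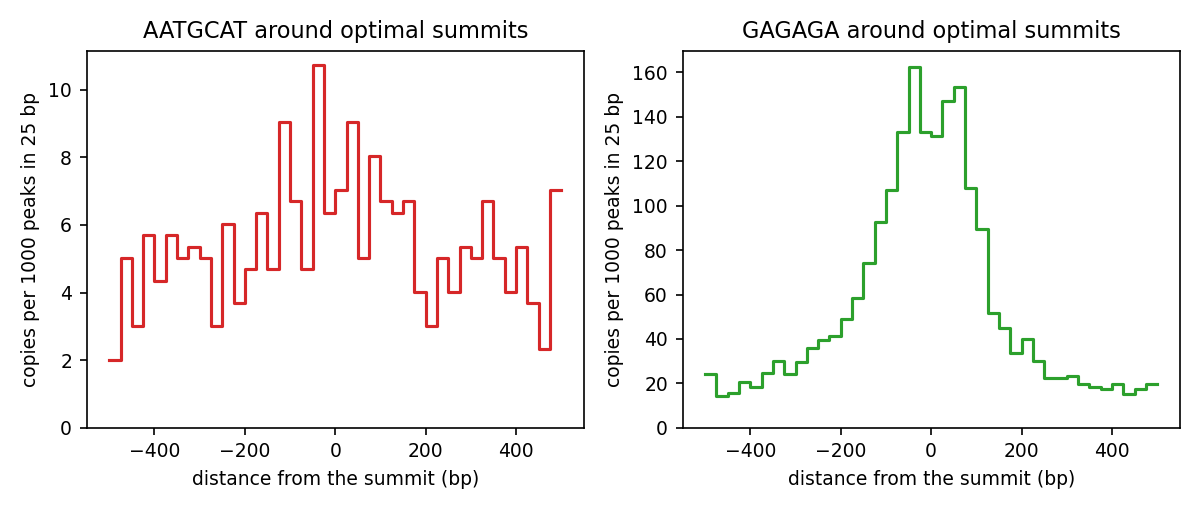
Copies of AATGCAT (left) and GAGAGA (right) on either strand in bins of 25 bp around optimal summits (x axis, bp) per 1000 peaks (y axis, different scales). GAGAGA reaches 162 copies in a bin near the summit, and AATGCAT, with at most 10.7, is much rarer.

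Chromosome III carried the most peaks for its length and chromosome V the fewest. There were 39.8 optimal peaks per Mb on III, 36.6 on I, 32.6 on X, 28.4 on II, 26.7 on IV and 19.5 on V. The replicates' own peaks gave 39.3 ± 0.205 on III and 32.7 ± 0.559 on X (SD, n = 2). X held 19.3% of peaks (95% interval 17.9 to 20.8) and 17.7% of the length (exact binomial test, two-sided, adjusted p = 0.024). Among peaks with signals above the median the share on X was 17.7% (exact test, adjusted p = 0.946). III held 18.4% of peaks and 13.7% of the length (exact test, adjusted p = 5.1e-12), and V held 13.7% and 20.9% (adjusted p = 1.6e-23). On the autosomes, 41.95% of peaks (95% interval 39.97 to 43.95) lay in the middle section when each chromosome was cut into 3 equal lengths, which holds 38.1% of protein-coding genes.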

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

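In this part the known target counts, the density of weaker peaks at unc-86 and the tests of whether a sequence lies at most peaks of a pattern were chosen only after the result was seen. The rank of AATGCAT among sequences of the same composition and the matched lists for ribosomal genes were planned. What their outcomes would mean was written down only after the result was seen. For the other tests the pattern was known, but what each outcome would mean was written down before the test was run.

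Calls of the pooled list below the optimal threshold, which the tests of promoters and gene lists in the report leave out, lay at some known UNC-86 targets. Of the 7 known target genes without an optimal peak, 5 had a weaker peak of the pooled list in the promoter window: eat-4 (52.4), cho-1 (42.5), cfi-1 (41.5), mec-4 (33.6) and cat-1 (21.6). The peak at eat-4, 245 bp upstream of the 5' end, had AATGCAT within 75 bp of its summit. Of all protein-coding genes without an optimal peak, 33.005% had such a weaker peak (Fisher's exact test, two-sided, p = 0.043). Against random genes matched on upstream length, which gave 35.7%, the count of 5 was not past the threshold (permutation p = 0.124). The peak at cat-1 was near the bottom of the pooled list (rank 15757 of 20768) and had no counterpart in replicate 1. No peak of the pooled list was found at tph-1 and unc-17.

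AATGCAT was more frequent at summits than in flanks, and 3 explanations were weighed. Base composition is argued against, since the ratio was in the top 2.46% of sequences with the same number of A or T and of G or C bases, although finer composition was not matched. Peaks with GAGAGA at the summit do not account for it alone, since in the 1903 peaks without GAGAGA the odds ratio was 1.51 (95% interval 1.05 to 2.15). Related sequences, such as AGACGCAG at 14.4% of all optimal summits, were not set aside, so promoters of this wider kind are not excluded. Placement at the point of binding stays open: copies per base within 25 bp of the summit were 0.871 times those at 26 to 75 bp, with an interval of 0.585 to 1.28 that holds both outcomes.

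Ribosomal protein promoters carried peaks in 84.2% of genes. The length of upstream space is argued against, since the count was at percentile 100 of matched random lists, whose mean was 16.7%. Peaks at promoters used in all cells, whatever the factor, remain a candidate explanation: 53.5% (95% interval 44.5 to 62.3) of 129 proteasome, vacuolar ATPase, respiratory chain and translation factor genes had a peak, against 12.8% of other genes. AATGCAT does not account for most peaks at ribosomal protein promoters, as 2 of 61 had it (3.28%, interval 0.400 to 11.3, against 3.04% of the other peaks). The test whose meaning was written down beforehand could not decide, as this interval holds the share of the other peaks. A part at few promoters stays open. No tagged protein other than UNC-86 was analysed here, so no comparison between factors was made.

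At unc-86, 12 optimal peaks lay within 20 kb. Extra copies of the region in the transgene may account for the cluster: weaker peaks were dense too, 21 against a median of 7, above 99.5% of windows, though open chromatin at the locus would give the same. Some of the 21 overlapped an optimal peak, so their density is not fully separate from that of the cluster. Whether the control held the same extra copies is not known. GAGAGA lay at 2 of the 12 (16.7%, interval 2.09 to 48.4), against 36.4% elsewhere. AATGCAT lay at 0 of them (upper bound 26.5%), against 3.06% elsewhere. The tests whose meaning was written down beforehand could not decide for either sequence, as each interval holds the share elsewhere. Both upper bounds were below 50%, a mark set after the values were seen and only just met for GAGAGA. By that mark, neither sequence lay at most of the 12. With 12 peaks, a smaller part for either sequence stays open. Binding of UNC-86 at other sequences near its own gene was not tested.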

How the results depend on the processing

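Of 59 recomputed values other than single lists and sequences, 51 were counted as kept. For shares and rank agreement this meant the same direction and side of the threshold or a move of less than their spread. Counts of lists or sequences were judged by fold change only, so a change from 10 lists to 7 or 12 was counted as kept. For single lists 253 of 270 were kept, with 10 newly past the threshold and 7 no longer past it, and for sequences 57 of 63. A list or sequence past the threshold in neither setting was counted as kept even if its direction changed. The serotonin pathway went from 16.7% (13.1% of other genes) to 0% (8.97%) with the nearest 5' end only. No value reversed past the threshold. Leaving out each replicate in turn moved no call of the promoter share, the AATGCAT ratio or chromosome X. The touch receptor list passed without replicate 2 (Fisher's exact test, adjusted p = 0.049), but not against matched lists (permutation test, adjusted p = 0.089). Its count was 5 of 13 as before, with mec-6 in place of mec-2. The 2 measures of agreement between replicates need both, so no replicate was left out there, and with 1 group no paired analysis was possible because no groups are compared.

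The share of optimal peaks in both replicates was 72.0% with 50% reciprocal overlap, 81.2% with summits within 100 bp, 82.0% for the lists on ce10, and 100% with the whole relaxed lists or among the optimal peaks with signals above the median. The relaxed lists are longer, which by construction raises the share, also by chance (8.73%). Among peaks with signals above the median rho was 0.880. With each peak given to the nearest 5' end only, 3 lists rather than 5 had fewer peaks. The AATGCAT ratio was 1.5 among peaks above the median signal (fewer peaks), 1.57 within 30 bp (less sequence searched) and 1.32 with flanks at 1000 bp, each no longer past the threshold, and chromosome X held 17.7% of these stronger peaks. For the last 2 the cause was not tested. With the list of other genes used in all cells, added after seeing the data, 11 lists passed rather than 10. Around unc-86, 10 kb held 8 optimal peaks and 40 kb held 12. Read depth, which the lists do not give, limits which weak peaks could be called.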

Other observations

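All tests in this part were chosen after the data were seen. In the next 2987 peaks of the pooled list, ranks 2988 to 5974, touch receptor and pan-neuronal genes were more frequent than other genes. Among the 8 touch receptor genes without an optimal peak, 5 had one there (62.5%, Fisher's exact test, adjusted p = 0.0021), against 7.90% of other such genes: mec-6 (65.1), mec-12, an alpha-tubulin gene (60.8), mec-18 (45.2), mec-1 (42.8) and mec-17, a tubulin acetyltransferase gene (38.9). Of the 7 remaining pan-neuronal genes, 4 had one (exact test, adjusted p = 0.0085): unc-104, an axonal kinesin gene (61.3), unc-10 (46.96), aex-3 (45.1) and snn-1 (37.6). Of 27 neuronal fate transcription factors, 6 did (22.2%, exact test, adjusted p = 0.073), namely ahr-1, zag-1, cfi-1, ham-2, ceh-14 and egl-44. Of the 12 remaining ribosomal protein genes 5 did (exact test, adjusted p = 0.0092), and of 1297 chemoreceptor genes 11 did. Neuropeptide genes, low among optimal peaks, had 16 of 134 (11.9%, exact test, adjusted p = 0.350). The pooled list includes background, and a pooled call near unc-86 with a signal of 39.8 had a −log10 q of 1.11. The weakest calls named here, such as those at mec-17 and snn-1, may therefore be background.

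GAGAGA lay at 41.0% of summits in the strongest 746 optimal peaks, at 33.2% in the weakest 747, at 22.5% in ranks 2988 to 5974 and at 8.88% in the last 8820 peaks. AATGCAT lay at 2.28% of summits in the strongest 746, against 1.54% in flanks (Fisher's exact test, adjusted p = 0.274), and at 3.28% in ranks 2988 to 5974, against 1.74% in flanks (adjusted p = 5.0e-05). In weaker peaks it lay at 2.31% against 2.06% in ranks 5975 to 11948 and at 2.32% against 1.95% in the last 8820 (Fisher's exact test, adjusted p = 0.274 and 0.114). The difference between ranks was not tested.

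The commonest 8 base sequences at summits by difference from flanks were not repeats of GA alone. AGACGCAG lay at 14.4% of summits and 0.921% of flanks, and GAGACGCA at 13.6% and 0.787%. Which protein binds these sequences was not tested.

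Among the 100 strongest optimal peaks 27 lay on chromosome III, which is 13.7% of the length (exact binomial test, adjusted p = 0.0023), and 8 lay on V, which is 20.9%. Of genes used in all cells beside those of ribosomal proteins, peaks lay at the promoters of 18 of 33 proteasome genes, 8 of 20 vacuolar ATPase genes, 20 of 37 respiratory chain genes and 23 of 39 translation factor genes (Fisher's exact test, adjusted p from 5.0e-11 to 0.0025).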
